A study of Rattus norvegicus with 15 samples.

How the data were processed

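RNA was sequenced from Achilles tendons of 5 male Sprague-Dawley rats aged 8 weeks. Each tendon was cut into equal proximal, middle and distal segments, and the same segment of both limbs was combined before RNA isolation, per the labels' protocols. This gave 15 poly(A)-selected, strand-specific, paired-end libraries, 1 per region and rat. The labels name the rat of every library, so the 5 rats are the replicates and each rat contributes all 3 regions. Mechanical measurements belong to the same study and were not analysed here.

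The deposited table holds raw read counts per Ensembl rat gene, made by the authors and not normalized. Per the submitters' processing notes, fastp 0.19.10, HISAT2 2.2.1, SAMtools 1.9, featureCounts 2.0.1 and the rn6 genome build were used. Options, annotation release and strand setting are not given in the sources used here. It is therefore unknown how reads from overlapping or antisense genes, and from genes with near-identical copies, were assigned in these counts. The table has 32883 genes, of which 10178 were at 0 in all libraries, and no row without a gene identifier. All 15 columns were matched to samples by region and rat in their names. Library totals ran from 15413963 to 30178952 counts. Counts of the closest pairs of same-region libraries differed by far more than sampling noise (chi-square per degree of freedom at least 20.4), so no library was a copy of another of its region. Pairs from different regions were not compared in this way.

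The table identifies genes only by Ensembl identifiers, and the gene table used here (assembly GRCr8) pairs 0 of the 32883 identifiers with a symbol. The marker and pathway gene lists, the set tests on them, the panel of tendon genes and the muscle-marker adjustments that were fixed before the data were examined could therefore not be applied. For proximal against distal, 2 identifiers that were higher and 2 that were lower are printed, and none for the other comparisons. They are those with the largest fold change between proximal and distal that passed the threshold, averaged at least 1 log2 CPM and had the same sign in all 5 rats. This is the rule fixed beforehand for named genes without its condition on symbols.

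Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with region as the group (15037 genes, with 99.9% of the counts in the library where their share was lowest), scaled by TMM and fitted with a robust quasi-likelihood model with terms for region and rat over all 15 libraries. Contrasts were proximal against distal, middle against distal, proximal against middle, any region (an F test) and middle against the mean of both ends. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Standard errors of log2 fold changes were derived from the fold change and the quasi-likelihood F statistic. They are approximate, since that statistic comes from a likelihood ratio, and they do not measure the spread between rats. Log2 CPM values used a prior count of 2. Identically numbered libraries come from the same animal. Their deviations from the region means were positively correlated (r over 0.1) in 13 of the 15 same-rat pairs, and on genes without a region difference all 15 libraries followed the other libraries of their own rat most closely, the proximal library of rat 4 by a narrow margin (r = 0.210 against 0.204 for the next rat).

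The position of a library on the distal-to-proximal axis was its projection, over all tested genes, on the line from the mean distal (0) to the mean proximal library (1) of the other 4 rats. Single values per library were compared by exact two-sided permutation of the 3 region labels within each rat (7776 arrangements, statistic proximal minus distal), with Benjamini-Hochberg adjustment over the 7 measures tested. For the distance of a library from its region, the distances were recomputed under each arrangement. The 7 measures, the axis position and the correlations between rats were chosen after a first look at the data. Correlations between rats were computed across genes, which are not independent replicates, and never between differences that share a library. Proximal-end and distal-end genes were chosen after seeing the data, from rats 3 and 4 alone, as genes at least 3 log2 units apart between proximal and distal in both rats and at least 10 CPM at the higher end. Those rats were picked after the levels per library had been seen. A difference of 5 log2 units was tried first and gave 71 proximal-end and 4 distal-end genes. It was lowered to 3 after these sizes were seen, which gave 112 and 16.

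The model was tested on simulated data with the real library sizes, gene means and dispersions, with 100 genes changed at each fold size. For proximal against distal it recovered 76% of 2-fold and 92% of 4-fold changes, and 6.67% of its calls were false. For middle against distal it recovered 76% of 2-fold and 24% of 1.41-fold changes, and for proximal against middle 73% and 27%, each among 14921 genes. A random rat effect of a set size was added to the simulated counts. Far fewer genes were changed than were called in the real data. No simulated library differed from others of its region in a whole group of genes, as real proximal libraries did, so these rates may not carry over. Alternatives fixed beforehand were the fit without the rat block, other size factors, DESeq2 1.42.0, limma 3.58.1 with quality weights, other low-count filters, 2-region fits, a 2-fold minimum and leaving out each rat. Leaving out each library, thinning to one depth, leaving out abundant or proximal-end genes and a proximal-end covariate were added after seeing the data.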

Results

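Gene expression was measured along the length of the rat Achilles tendon, in the proximal, middle and distal segments of 5 rats, to describe how the tissue differs along its proximal-distal axis. Each region gave 5 libraries, 1 per rat. Distal libraries held 23530376 to 30178952 gene counts, middle libraries 18866801 to 27817554 and proximal libraries 15413963 to 22205927. The proximal library was shallower than the distal library in 5 of 5 rats (p = 0.00257, adjusted p = 0.00900, two-sided exact permutation of region labels within rats). After thinning all libraries to the smallest total, 17788 ± 133 genes had at least 1 count in distal, 17953 ± 81.1 in middle and 17977 ± 254 in proximal tendon. Proximal and distal did not differ in the test (p = 0.101, adjusted p = 0.176, exact permutation), and the middle was not tested.

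A few genes made up a large part of every library. Genes are ranked here by their mean share over all 15 libraries, and in distal tendon the third gene lay above the second. The most abundant gene took 10.7 ± 0.984% of counts in distal, 12.3 ± 4.56% in middle and 12.3 ± 7.24% in proximal tendon. Its proximal and distal shares did not differ in the test (p = 0.547, adjusted p = 0.547, exact permutation), and the middle was not tested. The second most abundant gene stood at 3.90 ± 0.210%, 4.57 ± 1.10% and 4.54 ± 1.86%, and its proximal and distal shares did not differ either (p = 0.370, adjusted p = 0.432, exact permutation). In proximal tendon the share of the most abundant gene ran from 4.25% in rat 5 to 23.3% in rat 1. The third most abundant gene fell along the axis in all 5 rats, from 4.55 ± 0.379% of counts in distal to 2.47 ± 0.758% in middle and 1.32 ± 0.508% in proximal tendon. Its proximal and distal shares differed (p = 0.000257, the smallest the exact permutation can give, adjusted p = 0.00180). The 10 most abundant genes together held 23.4 to 25.5% of distal, 10.8 to 30.4% of middle and 9.32 to 35.6% of proximal counts (p = 0.302, adjusted p = 0.423, exact permutation of proximal against distal).

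**Figure D1:**
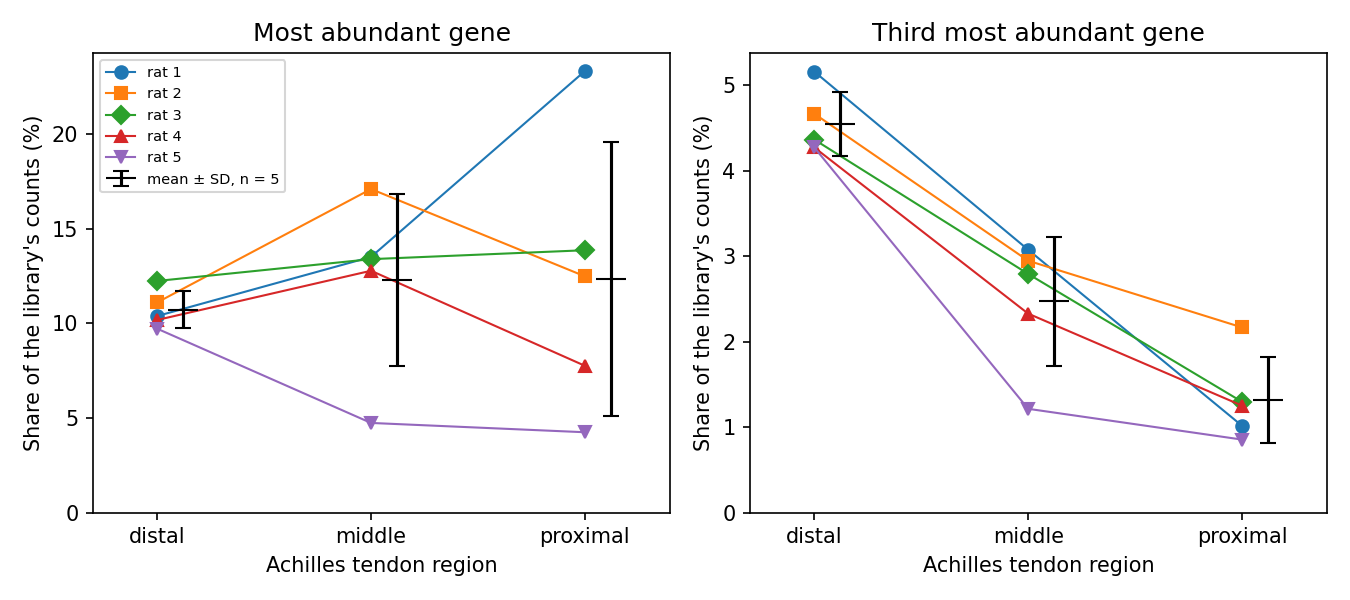
Share of each library's counts (percent, from 0) taken by the most abundant gene and by the third most abundant gene in the distal, middle and proximal segments, with 1 line per rat and black bars for mean ± SD (n = 5). Ranks are by mean share over all 15 libraries. The third most abundant gene falls from 4.55% in distal to 1.32% in proximal tendon and does so in every rat, while the most abundant gene spreads from 4.25% to 23.3% in proximal tendon.

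The transcriptomes of the 3 regions were ordered along the tendon in every rat. The first principal component of log2 CPM held 47.2% of the variance and placed distal, middle and proximal libraries in that order within each of the 5 rats. On the axis from the mean distal to the mean proximal library of the other rats, distal libraries lay at 0.0333 ± 0.106, middle libraries at 0.555 ± 0.259 and proximal libraries at 0.938 ± 0.316 (SD, n = 5), again in that order in 5 of 5 rats. The middle segments covered a wide part of this axis, from 0.288 in rat 1 and 0.318 in rat 2 through 0.602 in rat 4 and 0.654 in rat 3 to 0.915 in rat 5. Proximal segments ran from 0.505 in rat 2 and 0.711 in rat 1 to 1.25 in rat 5. The middle segment of rat 5 thus lay further along this axis than the proximal segments of rats 1 and 2. Genes with large differences between the ends weigh most in this projection, the proximal-end genes described below among them. With those genes left out, the mean middle position was 0.661, and the positions of single libraries were not compared. The root-mean-square distance of a library from the mean of the other rats' libraries was 0.401 ± 0.0351 log2 units in distal, 0.526 ± 0.126 in middle and 0.605 ± 0.132 in proximal tendon. The proximal value exceeded the distal value in 5 of 5 rats, but the difference did not pass the test (p = 0.0653, adjusted p = 0.152, exact permutation with distances recomputed for each arrangement).

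**Figure D2:**
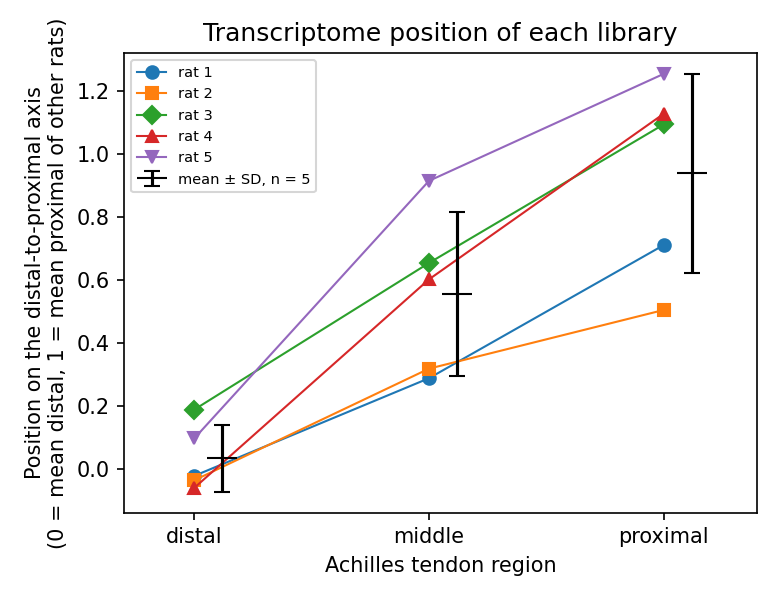
Position of each library on the axis from the mean distal (0) to the mean proximal (1) library of the other rats, by region, with 1 line per rat and black bars for mean ± SD (n = 5). Each line rises from distal to middle to proximal, and the middle segments lie between 0.288 and 0.915.

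The comparison of both ends asked which genes separate proximal from distal tendon. Of 15037 genes tested, 6300 differed (41.9%), 3331 higher in proximal and 2969 higher in distal tendon (edgeR quasi-likelihood test with rat as a block, adjusted p under 0.05). Most differences were small, with a median log2 fold change of 0.71 for genes higher in proximal and -0.56 for genes lower in proximal tendon. A change of at least 2-fold was found for 1101 genes higher in proximal and 802 higher in distal tendon, and one of at least 8-fold for 150 and 72 genes. The within-rat difference had the same sign in all 5 rats for 5533 of the 6300 genes (87.8%). Among all genes tested 44.3% had one sign in all rats, where chance gives 6.25%. Abundant genes leaned toward the distal end: of the 100 most abundant genes, 43 were higher in distal and 13 in proximal tendon. The genes higher in distal tendon made up 37.5% of distal and 21.7% of proximal counts, and the genes higher in proximal tendon 21.3% of proximal and 11.2% of distal counts, shares computed in the same libraries in which the genes were called. With the mean level of the proximal-end genes described below as a covariate, a setting chosen after seeing the data, 2218 genes passed, 1152 higher and 1066 lower in proximal tendon. The median level of those genes was itself higher in proximal than in distal tendon in 5 of 5 rats. The covariate thus overlaps with region, and lost precision was not separated from a lost difference. With the proximal-end genes left out instead, also set after seeing the data, 6191 genes passed.

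Among the genes with the largest differences, ENSRNOG00000061160 was measured at 630 ± 186 CPM in distal, 72.4 ± 105 in middle and 2.62 ± 0.734 in proximal tendon (SD, n = 5). It fell by 8.25 ± 1.40 (approximate SE) on the log2 scale from distal to proximal (edgeR, adjusted p = 0.00134). Its within-rat difference in log2 CPM, proximal minus distal, was -7.85 ± 0.431 (SD, n = 5). ENSRNOG00000004278 followed the same course, from 65.8 ± 21.1 CPM in distal through 7.50 ± 11.1 in middle to 0.303 ± 0.255 in proximal tendon. Its proximal-to-distal log2 fold change was -8.38 ± 1.31 (approximate SE, edgeR, adjusted p = 0.000854), and its within-rat difference -7.69 ± 1.49 (SD, n = 5). The middle values of both genes came mainly from rats 1 and 5. There ENSRNOG00000061160 stood at 239 and 113 CPM, against 2.41 to 4.09 CPM in the middle libraries of the other rats. At the other end, ENSRNOG00000016983 was at 0.241 ± 0.226 CPM in distal and 1740 ± 1855 CPM in proximal tendon, a log2 fold change of 12.59 ± 2.59 (approximate SE, edgeR, adjusted p = 0.00382). It had only 28 counts over all 5 distal libraries, so the size of this fold change is uncertain. Its within-rat difference in log2 CPM was 9.95 ± 4.91 (SD, n = 5). Its proximal value ranged from 0.386 CPM in rat 2 and 126 CPM in rat 1 to 4532 CPM in rat 3. ENSRNOG00000030848 had only 4 counts over all 5 distal libraries, too few for a fold change, and 383 ± 395 CPM in proximal tendon (edgeR, adjusted p = 0.000444), where it ranged from 1 count in rat 2, whose distal library had 0, to 15833 counts in rat 5. The proximal-end covariate is built from genes that include both of these higher ones, so their loss under it is no independent evidence. With it neither of these higher genes passed, and both lower genes did. The adjusted p (edgeR) of ENSRNOG00000016983 was then 0.680, the highest over its alternatives, at a log2 fold change of 1.02, and that of ENSRNOG00000030848 was 0.390, also its highest.

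A wider set was chosen after the values per library had been seen. The 112 proximal-end genes, chosen in rats 3 and 4 alone, whose proximal libraries were among those known to be high, had a median level of 106 and 51.8 CPM in the proximal segments of those rats. In the rats not used to choose them, the median was 89.5 CPM in the proximal segment of rat 5, 6.21 CPM in that of rat 1 and 0.579 CPM in that of rat 2, the last close to the 0.510 to 0.652 CPM of the distal segments. The set took 3.91% of all counts in the proximal segment of rat 5 and 0.0317% in that of rat 2. In the middle segments it lay between 0.707 and 0.980 CPM, except in rat 5, where it reached 12.1 CPM. A set of 16 distal-end genes was chosen the same way. Its median was 21.9 to 38.5 CPM in distal and 1.42 to 2.28 CPM in proximal segments. In rats 1, 2 and 5, not used to choose the set, it was 21.9 to 37.9 CPM in distal and 1.60 to 1.82 CPM in proximal segments. In the middle it stood at 19.9 CPM in rat 1 and 6.93 CPM in rat 5 and at 1.68 to 2.99 CPM in the other rats.

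**Figure D3:**
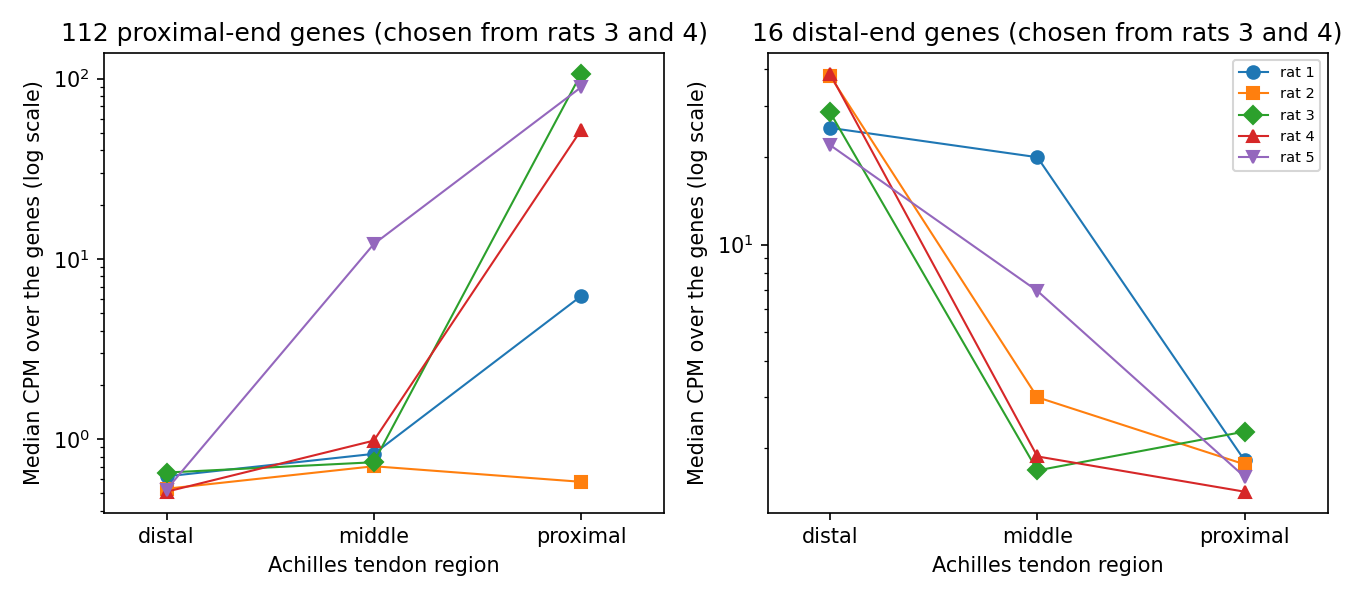
Median CPM (log axis) of the 112 proximal-end genes and the 16 distal-end genes, both chosen from rats 3 and 4, in the distal, middle and proximal segment of each rat (1 line per rat). The proximal-end genes reach 106 CPM in the proximal segment of rat 3 but 0.579 CPM in that of rat 2, and in the middle segment of rat 5 both sets stand above those of rats 2, 3 and 4.

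The comparison of middle with distal tendon gave 3731 genes (24.8%), 1986 higher and 1745 lower in middle tendon (edgeR quasi-likelihood test with rat as a block, adjusted p under 0.05). The medians were 0.71 and -0.58 on the log2 scale. At least 2-fold changes were found for 577 genes higher and 470 genes lower in middle tendon, and 23 and 30 genes changed at least 8-fold. Of the 100 most abundant genes, 29 were lower and 8 higher in middle than in distal tendon. All 5 rats had the same sign for 3403 of the 3731 genes (91.2%), and for 34.9% of all genes tested. Of the 16 distal-end genes, 15 were called in this comparison, and of the 112 proximal-end genes 11 were, both sets having been chosen with the distal libraries of rats 3 and 4. Without the rat block 2303 genes passed, and without the distal library of rat 4 the count was 2266.

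The comparison of proximal with middle tendon gave 62 genes, 41 higher and 21 lower in proximal tendon, of which 24 and 5 changed at least 2-fold (edgeR quasi-likelihood test with rat as a block, adjusted p under 0.05). None of the 100 most abundant genes was among them. The same sign was seen in all 5 rats for 57 of the 62 genes (91.9%), and for 2637 of all genes tested (17.5%). Of the 112 proximal-end genes 11 passed, and of the 16 distal-end genes 0 passed. At an unadjusted p under 0.05 there were 3100 genes. The count depended on the method and on single libraries: DESeq2 gave 1198 genes, limma 396 and the fit without the rat block 0. Leaving out the proximal library of rat 2 raised it to 536, which included all 62, leaving out the middle library of rat 5 or the distal library of rat 5 raised it to 129 or 131, and the other libraries left out in turn gave 0 to 76 genes, with 0 without the middle library of rat 2 or the proximal library of rat 3.

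**Figure D4:**
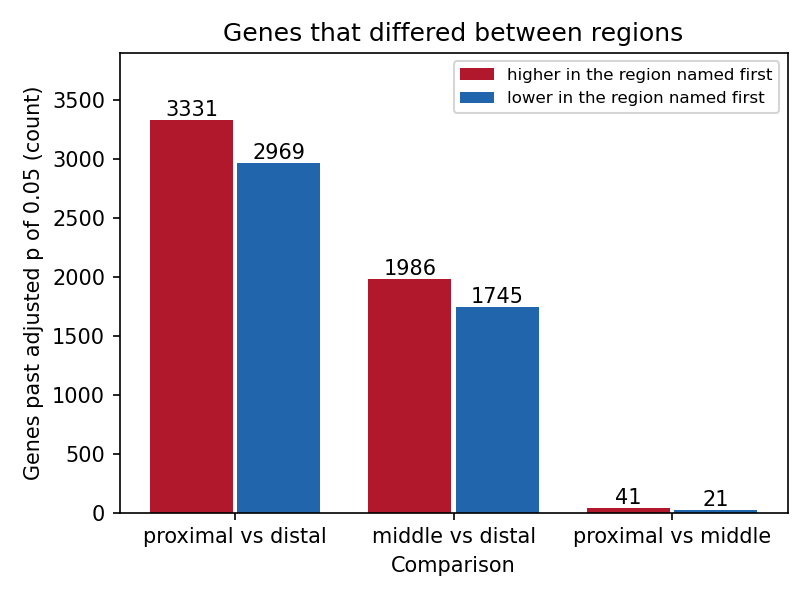
Number of genes past an adjusted p of 0.05 (edgeR) in each pairwise comparison, split into genes higher (red) and lower (blue) in the region named first. Proximal against distal gives 3331 and 2969 genes, middle against distal 1986 and 1745, and proximal against middle 41 and 21.

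The F test of any difference between the 3 regions called 5629 genes (37.4%; edgeR, adjusted p under 0.05). By fitted means, 2410 of them rose from distal through middle to proximal and 2177 fell in that order, so that the middle lay between both ends for 4587 genes (81.5%). The middle was highest or lowest for the remaining 1042 genes. These are means over rats, and a mean in between can come from averaging unlike middle segments. The distal-end genes, for example, were near the distal level in the middle of rat 1 and near the proximal level in that of rats 2, 3 and 4. The F test called 3262 genes without rat 4 and 2798 with the proximal-end covariate, and the order of the regions was not counted in those settings. A test of the middle against the mean of both ends called 0 genes (edgeR, smallest adjusted p = 0.0923), with 2316 genes at an unadjusted p under 0.05. In the same contrast limma called 4 genes and DESeq2 594.

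The likeness of the rats was measured by correlating within-rat differences across genes between rats, which share no library. The correlations are across genes, which are not independent replicates. For proximal minus distal, the 10 pairs of rats had a mean r of 0.644 (range 0.398 to 0.839), and for middle minus distal a mean r of 0.526 (0.364 to 0.687). For proximal minus middle the mean r was 0.330 (0.0281 to 0.726), with rat 2 at a mean of 0.0869 against the other rats. The step from distal to middle in one rat was correlated with the step from middle to proximal in another at a mean r of 0.193, positive in 15 of 20 ordered pairs and ranging from -0.102 to 0.453.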

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

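All tests in this part were chosen after the results were seen, and the sets of end genes they use were themselves chosen, and their threshold lowered, after the values per library had been seen. Of 48 sets of 5 libraries screened for 1 library far from the rest, 4 held one, where chance alone gives about 2.4 sets (5%). All 4 were the middle library of rat 5, and the 4 measures are not independent, since both genes given here are among the proximal-end genes. Its distance from the mean of the other middle libraries was 0.745 log2 units, against 0.445 to 0.521 for the others. Its median level of the 112 proximal-end genes was 3.60 log2 CPM, against -0.33 to 0.0955. ENSRNOG00000030848 stood at 6.24 log2 CPM (others -1.76 to -0.96) and ENSRNOG00000016983 at 8.44 log2 CPM (others -0.16 to 0.57).

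A library of another rat is argued against, since on genes with no region difference this library's correlation with the other libraries of rat 5 exceeded its best correlation with another rat by 0.279. A swap of the middle and proximal labels of rat 5 is argued against too, since the library labelled proximal lay 0.601 axis units above the highest of the other middle libraries. Relative to the median of the other middle libraries, the distal-end genes were raised by 1.53 and the proximal-end genes by 3.80 log2 units, so a candidate explanation is that this segment held material from toward both ends. The middle library of rat 1 had the higher level of the distal-end genes (19.9 against 6.93 CPM). The labels name no property that sets rat 5 apart, and no biological explanation was tested.

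A second pattern is the spread of the proximal-end genes between proximal libraries, with a median proximal minus distal difference of 7.08 log2 units in rat 5 and 0.345 in rat 2 (8.39 and 0.293 for the 71 genes of the threshold tried first). Among the 67 of these genes under 1 CPM in distal tendon, a restriction also set after seeing the data, the SD over genes of the log2 ratio to the proximal libraries of rats 3 and 4 was 0.658 in the proximal library of rat 1 and 0.401 in the middle library of rat 5, at median log2 ratios of -4.18 and -2.83. In the proximal library of rat 2 the ratios were not kept (SD 2.34, r = 0.0644 across genes), at a median log2 ratio of -8.04, where counts are few. The nearly fixed ratios in the former libraries are consistent with 1 source present in different amounts, which may be material from near the proximal incision. A cell population within the tendon whose amount differs between rats would give the same ratios and stays open, since no cell type was assigned without gene names.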

How the results depend on the processing

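Leaving out single libraries, thinning, leaving out the 10 most abundant or the proximal-end genes, and the proximal-end covariate were chosen after seeing the data. The proximal-distal count was within 1.5 times of 6300 in 31 of 33 settings, and was 1903 with a 2-fold minimum and 2218 with the proximal-end covariate and replicate block. The middle-distal count of 3731 was 2303 with no replicate block, 1047 with a 2-fold minimum and 1849 to 3780 with a rat or library left out (1849 without rat 4, 2266 without its distal library). The proximal-middle count of 62 moved in 24 of 33 settings. It was 0 with no replicate block and with the covariate, 19 in a fit of only these regions, 29 with a 2-fold minimum, 396 with limma, 1198 with DESeq2, and 0 to 536 with a rat or library left out. The any-region count of 5629 was 2798 with the covariate and 3262 to 5568 with a rat or library left out, the lowest without rat 4. The middle-against-ends count of 0 was 594 with DESeq2, 4 with limma, 1 without the low-count filter and 0 to 11 with a rat or library left out, the highest without the distal library of rat 3. A 2-fold minimum counts fewer genes by construction. For the other changes, those from left-out rats and libraries included, the cause was not tested. The replicate block changed no other count by over 1.5 times. None of the 4 printed identifiers changed direction. Both higher ones lost their calls under the covariate, which is built from genes that include them, and both lower ones passed in 32 of 32 settings. ENSRNOG00000016983 passed in 30 of the 31 settings that tested it and ENSRNOG00000030848 in 29 of 30. ENSRNOG00000030848 was not among the genes tested in the fit of only proximal and distal libraries. The mean middle position was 0.491 to 0.661 over 14 settings, the highest with the proximal-end genes left out. Under the other size factors the counts stayed within 1.5 times. The muscle-marker settings and the gene list tests with their alternatives were not run, for lack of gene names.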

Other observations

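The counts from thinned libraries and the regroupings within rats were added after the data had been examined, and the other splits of the libraries were set before. The lower depth of the proximal libraries is argued against as the source of the proximal-distal count, since 5947 genes passed with all libraries thinned to one total, against 6300 at full depth.

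Each pairwise comparison was refitted on other splits of its 10 libraries. The splits that part every rat's pair, as the real one does, number 16, too few for a share under 0.05. Among these 16 splits only 1, the real one, reached the real count in each comparison. It was 6300 genes for proximal against distal (highest other 1), 3731 for middle against distal (highest other 0) and 62 for proximal against middle (highest other 0). Splits that leave some pairs together were run too, up to 100 in all, and were set before as the test of chance. They do not keep the pairing by rat on which the model rests, so no verdict is drawn from them. Their highest counts were 2046, 684 and 335 genes, each after exchanging 1 library per side. The 335 genes for proximal against middle, more than the real 62, came from exchanging the proximal library of rat 2 with the middle library of rat 5.

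For the F test of any region, the region labels were regrouped within each rat, and 100 of the 1296 such splits were fitted. Only 1 of the 100, the real one, gave 5629 genes, which argues against chance as the source of this count but does not exclude it. The highest others gave 3832 and 3741 genes after changing the labels in 2 rats. Both only exchanged middle and proximal labels and kept every distal label. The remaining regroupings, which each moved a distal library, gave at most 15 genes. The regrouping thus bears mainly on distal against the other regions. Most of the 1296 splits were not fitted, and none of those fitted changed the labels in only 1 rat. For the middle against both ends the real count was 0, so that all 100 splits tried reached it by construction and their number decides nothing. These splits regrouped all 15 libraries without regard to rat, and the highest gave 4193 genes.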
